A study of Mus musculus with 6 samples.

How the data were processed

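The samples were 6 anti-m6A IP libraries from pooled fetal hearts of FVB/NJ mice, 3 from sham and 3 from nano-TiO2 exposed litters. Per the labels' protocols, 3 µg of total RNA per sample was fragmented to roughly 250 to 350 nucleotides, bound to 5 µg of a polyclonal anti-m6A antibody and amplified over 10 PCR cycles and 8 indexing cycles with a low-input kit. The labels also describe input libraries; input reads were not used here. Groups and replicate numbers came from the sample titles.

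The authors deposited 3 tables with the same rows, an Ensembl gene ID with a window start, and 6 columns. Per the submitters' processing notes, HISAT2 2.2.1, Salmon 1.5.2, DESeq2 1.34.0 and the genome build GRCm39 were used, with no role or order given. How windows were made and counted, and with which strand setting, is not given in the sources used here. Per the labels and file headers, the deposited normalized table holds IP signal per window with no unit named. Its values were checked: every value was a whole multiple of 1 step per library, within a tolerance of 0.0001, in 100% of values, so it holds reads divided by 1 size factor per library, and whole reads were recovered from it. Median-of-ratio factors computed from gene totals were 0.917 to 1.138 times the deposited ones. The table named filtered was identical to the normalized one. The deposited adjusted table holds whole-number scores. In all 162014 pairs of gene and library with reads, the adjusted windows could be had from the normalized ones with 1 factor and rounding, and there were 0 exceptions. That factor averaged close to 1 over the 6 libraries of a gene (0.942 to 1.06). It is not stated what the factor was made from; a level of the gene in the input libraries is a natural reading, and it was not settled here. The factor could be recovered to within a relative width of 0.2 for 13812 genes. Genes with no read in any library numbered 14967, and the median gene had 63 windows.

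Window values were summed per gene. Genes, or windows, with a mean of at least 10 over the 6 libraries were tested with limma 3.58.1 (trend) in R 4.3.3 on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05 and no covariates. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. Windows within genes were tested with limma's diffSplice in genes with at least 2 tested windows. Per-library values were compared with exact permutation tests of 3 against 3 (SciPy 1.17.1), whose smallest two-sided p is 0.1, and adjusted over the 17 values compared. Thinning drew reads at random to the lowest library's total. These analyses ran on deposited tables only, in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6; figures used matplotlib 3.10.9. The unit of the tables differed from raw counts, so limma was the main test and the count tests edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. They called 6727 and 7077 genes in IP level, against 6676 with limma.

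Libraries held 20205024 to 31523675 reads in 997523 to 1484331 windows. Floors of 3 reads cover counting error only, since PCR copies are not independent molecules. The tests were tried on simulated data with 200 features changed. For IP level, reads were drawn, with each gene's own dispersion for genes and the median of these for all windows. Real windows may vary more or less than that. For adjusted level and the factor, normal values were drawn with each feature's own spread. Shares recovered and false calls are therefore not comparable between these kinds of simulation. For IP level per gene (18566 genes), 3.0% of 1.5-fold, 29.9% of 2-fold and 77.3% of 4-fold changes were recovered. For the adjusted level per gene (19361 genes) the shares were 19.4%, 49.3% and 66.7%, for the factor (13812 genes) 3.0%, 37.3% and 86.4%, and for IP level per window (250317 windows) 1.5%, 10.4% and 83.3%. The within-gene test (249423 windows) recovered 1.5%, 9.0% and 83.3%, with 21 false calls among 83, of which 2 lay in genes with a changed window. For IP level per gene there were 8 false calls among 81 by limma and 10 among 83 by edgeR. False calls numbered 1 among 91 for adjusted level per gene, 4 among 88 for the factor and 0 among 63 for IP windows.

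The RefSeq gene table at hand pairs no Ensembl ID with a symbol: 0 of 48505 IDs matched. The gene lists fixed before the data were examined therefore could not be tested, and no coordinates are given. The rule for named genes, also fixed then, took in each comparison per gene the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, or, where fewer than 10 passed, the 10 with the smallest p, and per window 5 rises and 5 falls. It passed over IDs with no symbol. Since no ID has one, that exception was set aside for the IP level. The first 2 IDs of each direction are printed, and the rest are summarised. No ID was chosen from the other comparisons. The 4 genes with the most reads were added after their values were seen. Near-identical gene copies may share reads in ways the window counts do not show.

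Alternatives fixed before the data were examined were pseudocounts of 0.5 and 5, looser and stricter filters, TMM and quantile normalization, array quality weights, edgeR and DESeq2, the median of a gene's windows, the replicate number as a block, and leaving out each library. For the position along genes they were genes with at least 20 windows, the last 10% of windows and a mean over genes. Added after the data were examined were the tests of the factor, removal of the length trend (loess on log2 windows per gene, span 0.3), scaling to equal totals with and without the 4 most abundant genes, edgeR with the factor as an offset, thinning, and the groups by length and level.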

Results

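N6-methyladenosine (m6A) is a methyl mark on RNA that is mapped by binding RNA fragments to an anti-m6A antibody and sequencing what is pulled down, the immunoprecipitate (IP). Here IP libraries were made from the hearts of wild-type FVB/NJ mouse fetuses whose dams had breathed either filtered air (sham) or an aerosol of engineered titanium dioxide nanoparticles (nano-TiO2). The target concentration was 12 mg/m3, given for 360 minutes on each of 6 days within an 8-day span that began on gestational day 5, and hearts were collected on gestational day 15. The series held 3 sham and 3 nano-TiO2 libraries, each from pooled hearts of male and female fetuses. The labels do not say how litters were divided among the pools, so p-values here measure only the spread between these 6 samples.

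The deposited values covered 5193362 windows, most of them starting 25 nucleotides apart, in 48505 genes given by Ensembl ID. Reads recovered from the values numbered 30862986, 31523675 and 22151447 in sham replicates 1, 2 and 3, and 20205024, 24031476 and 28251706 in nano-TiO2 replicates 1, 2 and 3. Between 25574 and 28353 genes had a read in a library. The files do not pair IDs with gene symbols, so genes are described as groups by length and level, and few are named.

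The sham IP libraries were more concentrated in a few very abundant transcripts than the nano-TiO2 libraries. ENSMUSG00000069917, ENSMUSG00000069919, ENSMUSG00000073940 and ENSMUSG00000052305, singled out after their values were seen because they held the most reads, took 25.95% ± 8.1 (SD, n = 3) of reads in sham and 13.6% ± 5.1 (SD, n = 3) in nano-TiO2 hearts. Their share was 35.2% in sham replicate 2 and 8.03% in nano-TiO2 replicate 2, the highest and lowest of the 6 libraries. The next 100 genes in abundance also took more of the remaining reads in sham, 28.9% ± 0.98 (SD, n = 3), than in nano-TiO2, 24.5% ± 2.0 (SD, n = 3). Nano-TiO2 libraries held reads in 1390168 ± 108000 windows (SD, n = 3) against 1080188 ± 75400 in sham, and in 27784 ± 832 genes against 26221 ± 596 in sham. With every library thinned to 20205024 reads, the windows with a read numbered 1320053 ± 77200 in nano-TiO2 and 968318 ± 25300 in sham (SD, n = 3). In each of these comparisons the 3 libraries of a group lay on one side of the 3 of the other, which gave p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 allow, and an adjusted p of 0.131 over the 17 values compared per library.

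**Figure D1:**
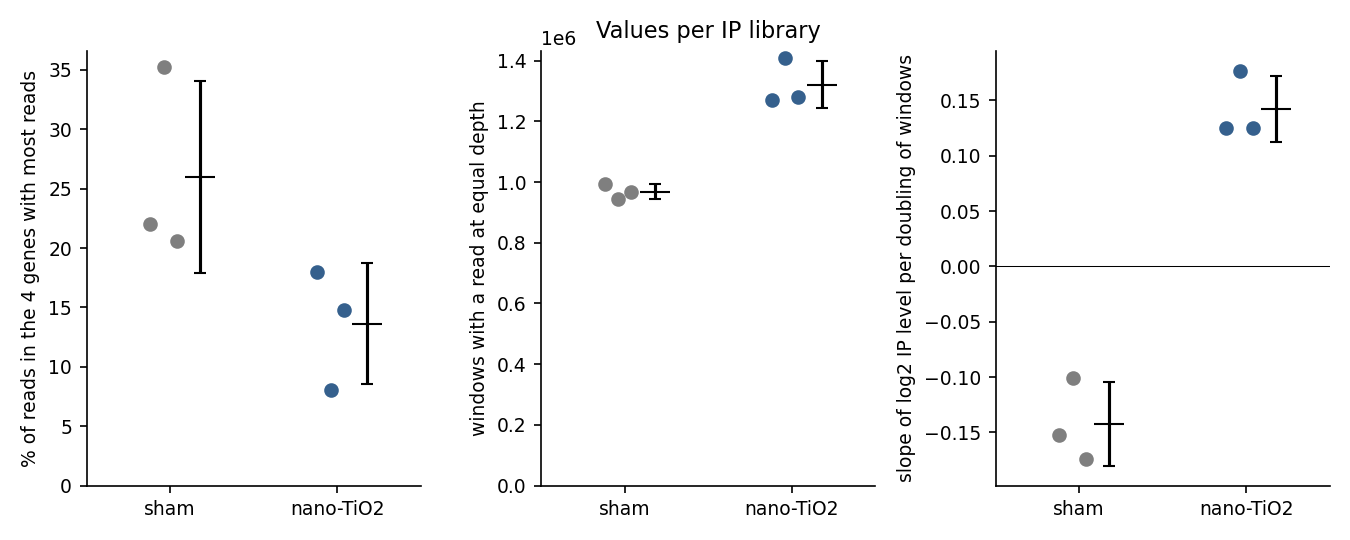
Values of the 3 sham and 3 nano-TiO2 IP libraries (points) with group mean and SD (bars): share of reads in the 4 genes with most reads (%), windows with at least 1 read after thinning to equal depth, and the slope of a library's log2 IP level, relative to the gene's mean over all libraries, on log2 windows per gene. The slopes are relative, so opposite signs of the group means are built in. In each panel the points of the groups do not overlap, and the slopes lie between -0.174 and -0.101 in sham and between 0.125 and 0.177 in nano-TiO2.

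The first comparison asked which genes differed in IP level, summed over their windows, between nano-TiO2 and sham fetal hearts. Of 18566 genes tested, 4450 rose and 2226 fell, with median changes of 2.14-fold among those that rose and 1.70-fold among those that fell. Changes of at least 2-fold were found in 2636 genes that rose and 429 that fell. In 6628 of the 6676 called genes the groups did not overlap; over all genes tested this held for 49.5%, where chance gives 10%. These are limma tests on log2(normalized value + 1) at an adjusted p of 0.05. The balance of rises and falls depended on scaling, and it differed in a fit that changed both the summary of windows and the genes tested. With the median of a gene's tested windows in place of the sum, 727 rose and 2074 fell among 8877 genes tested. Only genes with a window past the level filter entered that fit. The sum was not fitted to these genes alone, so the summary and the choice of genes cannot be told apart. The share of calls that were rises was 66.7% with the deposited scaling, 52.4% after quantile normalization, 86.2% with equal totals outside the 4 most abundant genes and 97.9% with equal totals, and these moved the median change of all genes from 0.13 to -0.05, 0.39 and 0.61 on the log2 scale.

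Direction followed gene length. Among the 20% of genes with the fewest windows (8 to 52), 171 rose and 1271 fell, and the median log2 change was -0.48 (interquartile range -0.80 to -0.04). Among the 20% with the most (266 or more), 2058 rose and 41 fell, and the median was 0.81 (interquartile range 0.31 to 1.24). The 3 groups in between had medians of -0.09, 0.12 and 0.34. Spearman's rho between windows per gene and log2 fold change was 0.55 across genes, which are not independent replicates, and 0.35 with no filter on low genes. Within each library, the slope of the log2 IP level, relative to the gene's mean, per doubling of windows was -0.152, -0.101 and -0.174 in sham replicates 1, 2 and 3 and 0.125, 0.177 and 0.125 in nano-TiO2 replicates 1, 2 and 3 (exact two-sided permutation p = 0.1, adjusted p = 0.131). For the values the authors call adjusted, the slopes of the groups overlapped, at -0.065, 0.039 and -0.094 in sham and 0.025, 0.053 and 0.042 in nano-TiO2 (exact permutation p = 0.2, adjusted p = 0.243). Both sets of slopes are relative to each gene's mean over the 6 libraries, so opposite signs of the group means are built in. With the length trend removed from each library, 4666 genes were called and 42.4% of them rose.

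**Figure D2:**
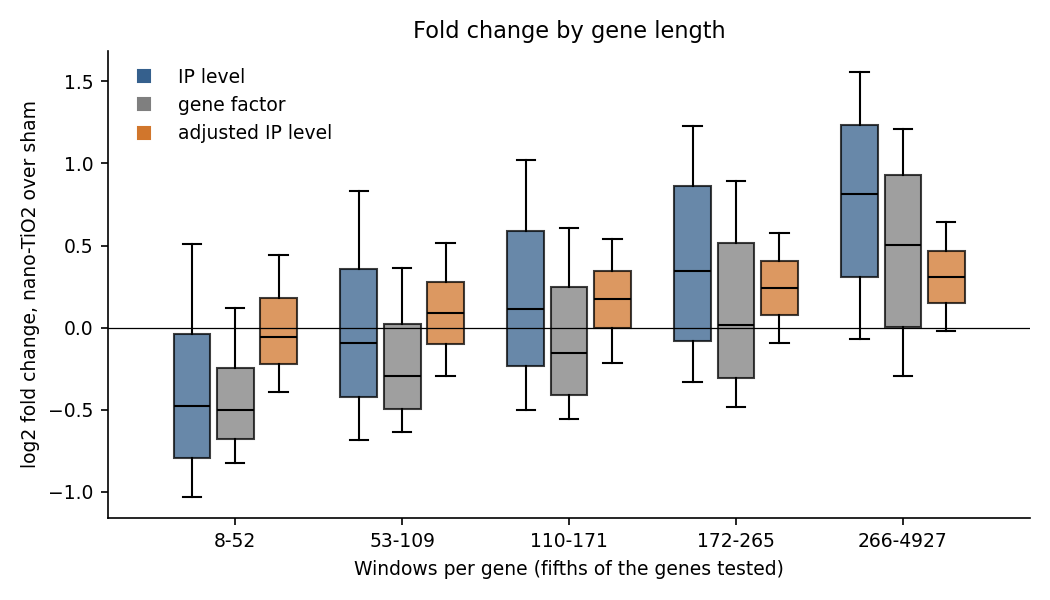
Log2 fold change (nano-TiO2 over sham) of the IP level, the gene factor and the adjusted IP level for genes in 5 groups by windows per gene; boxes span the interquartile range with the median as a line, and whiskers reach the 10th and 90th percentiles. The median IP change goes from -0.48 in the shortest to 0.81 in the longest genes and the median adjusted change from -0.06 to 0.31, while the adjusted slopes of single libraries overlap between the groups.

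Genes differed by abundance as well. Among the 20% with the highest mean IP level (970 normalized reads or more), 459 rose and 1207 fell, with a median log2 change of -0.27. In each of the 3 groups with the lowest levels more genes rose than fell, with medians between 0.27 and 0.34. The 4 genes with the most reads fell, with log2 changes of -1.58 to -1.40 (adjusted p 0.022 to 0.039, limma). Their decrease did not pass in any of the 4 without sham replicate 2 (-1.40 to -0.99, adjusted p 0.051 to 0.11), with the length trend removed (-1.23 to -1.02, adjusted p 0.11 to 0.14), with no filter on low genes (adjusted p 0.083 to 0.13) or with the median of the tested windows (adjusted p 0.057 to 0.059). Of the 4, 2 passed when sham replicate 1, sham replicate 3, nano-TiO2 replicate 2 or nano-TiO2 replicate 3 was left out, with changes of -1.13 to -0.89 without nano-TiO2 replicate 2. With equal totals outside these genes 2 passed (-1.31 to -1.13, adjusted p 0.044 to 0.064, limma). With equal totals 3 passed (-1.09 to -0.90, adjusted p 0.036 to 0.057, limma), and 3 passed with edgeR (adjusted p 0.015 to 0.052). After quantile normalization, which ties the top ranks of the libraries, their changes lay between -0.63 and 0.23.

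Of the genes whose groups did not overlap, the 10 largest rises reached 2.84 to 4.64 on the log2(value + 1) scale and the 10 largest falls reached -2.32 to -4.03. The largest rise was in ENSMUSG00000042459, which had 0 reads in the 3 sham libraries and 2, 35 and 199 in nano-TiO2 replicates 1, 2 and 3. Its mean of 63.8 ± 84.6 normalized reads (SD, n = 3) was at least 19.1-fold higher than the floor of 3 reads per sham library (adjusted p = 0.017, limma). Without nano-TiO2 replicate 3 the bound was at least 4.66-fold and the adjusted p 0.071. ENSMUSG00000114501 had 5, 0 and 0 reads in the sham libraries and 14, 45 and 35 in the nano-TiO2 libraries (log2 change 3.91 ± 0.76 SE, adjusted p = 0.0047, limma; 4.73 without sham replicate 1). ENSMUSG00000005681 went from 852 ± 1270 normalized reads in sham to 20.7 ± 14.0 in nano-TiO2 (SD, n = 3; log2 change -4.03 ± 1.14 SE, adjusted p = 0.023, limma). Sham replicate 2 held 2117 of the 2316 sham reads of that gene. Its log2 change was -2.55 without that library, -5.13 without sham replicate 1 and -3.42 without nano-TiO2 replicate 1, where the adjusted p was 0.06, and -3.59 with the length trend removed, where it was 0.053. ENSMUSG00000008843 went from 98.4 ± 136 to 3.76 ± 2.48 normalized reads (SD, n = 3; log2 change -3.46 ± 0.92 SE, adjusted p = 0.018, limma; 0.057 without nano-TiO2 replicate 3), with 233 of its 271 sham reads again in sham replicate 2. Its log2 change was -2.25 without that library and -4.15 without sham replicate 3. DESeq2 gave this gene no adjusted p. In the values the authors call adjusted, none of these genes passed with all libraries and no weights (limma). The log2 changes were 5.32 for ENSMUSG00000042459 (adjusted p = 0.18) and 2.39 for ENSMUSG00000114501 (adjusted p = 0.34). They were -0.53 for ENSMUSG00000005681 (adjusted p = 0.32) and -0.29 for ENSMUSG00000008843 (adjusted p = 0.77). ENSMUSG00000042459 passed without sham replicate 2 (5.32, adjusted p = 0.028, limma) and with array quality weights (5.11, adjusted p = 0.005, limma). ENSMUSG00000005681 passed with these weights (-0.78, adjusted p = 0.015, limma). ENSMUSG00000114501 and ENSMUSG00000008843 passed in neither setting. For the 2 that fell, the factor that divides sham replicate 2 was 5.37 and 5.48, against 0.32 or less in every other library.

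The next comparison used the values the authors call adjusted, which are the normalized IP values divided by one factor per gene and library. No gene passed at an adjusted p of 0.05 among 19361 tested (limma, smallest adjusted p = 0.179), and none passed with edgeR on recovered reads with the factor as an offset among 13808 tested. At an unadjusted p under 0.05 there were 3592 genes by limma, where chance gives 968, of which 3203 were higher and 389 lower in nano-TiO2, and 2863 genes by edgeR. The median adjusted log2 change was 0.17, and 69.5% of genes were higher in nano-TiO2; TMM scaling brought the median to 0.005. Among the genes that rose in IP level, the median change went from 1.09 before the factor to 0.36 after it, and 93.6% stayed on the same side of 0. Among those that fell it went from -0.77 to -0.16, and 85.2% stayed on the same side. These genes were chosen by their IP change, and the adjusted values are made from the same IP values. Part of the agreement in sign and of the smaller medians is therefore built in. The share of adjusted values in the 4 most abundant genes was 22.6% ± 1.5 in sham and 19.2% ± 1.6 in nano-TiO2 (SD, n = 3; exact permutation p = 0.1). Their adjusted log2 changes were -0.20 to -0.37 (adjusted p 0.18 to 0.22, limma). Without sham replicate 2, ENSMUSG00000052305 (-0.51, adjusted p = 0.028) and ENSMUSG00000073940 (-0.49, adjusted p = 0.03) passed, with array quality weights the 4 passed (adjusted p 0.005 to 0.03), and after quantile normalization their changes were 0 to 2 decimals. Without sham replicate 2, 1878 genes passed, 1611 of them higher in nano-TiO2, while none passed when any other library was left out. With array quality weights 5011 passed, 4347 of them higher; these weights were 0.37 for sham replicate 2, 4.46 for nano-TiO2 replicate 3 and between 0.58 and 1.77 for the other libraries.

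The factor itself, recovered for 13812 genes and not among the planned comparisons, differed between groups in 4979 genes, 2318 higher and 2661 lower in nano-TiO2 (limma, adjusted p under 0.05). Its log2 changes ran parallel to those of the IP level across 13806 genes (Pearson's r = 0.933, Spearman's rho = 0.925; genes are not independent replicates). Both were called in 3894 genes, 2196 higher in both and 1698 lower in both. Part of this relation is built in, since the factor was recovered as the normalized over the adjusted value, and other splits of the libraries gave correlations of 0.623 to 0.899. The factor changes also followed gene length, with medians of -0.50 in the shortest and 0.50 in the longest 20% of genes and a Spearman's rho of 0.56 across genes. The count of called factors depended on single libraries: no gene passed without nano-TiO2 replicate 1 or without nano-TiO2 replicate 3. At an unadjusted p under 0.05 (limma) there were still 5199 and 5610 genes without these libraries, against 7097 with all libraries. The median log2 change was -0.135 and -0.166, against -0.155, so the count fell to 0 without a large shift of the median. Among called genes the balance also turned, with 1373 higher and 319 lower without sham replicate 1, and 1233 higher and 195 lower without sham replicate 2. Over all genes the median log2 change stayed below 0 in these 2 fits, at -0.155 and -0.149. Centring each library on its median factor left 3595 calls and moved the share that was higher from 46.6% to 75.3%.

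**Figure D3:**
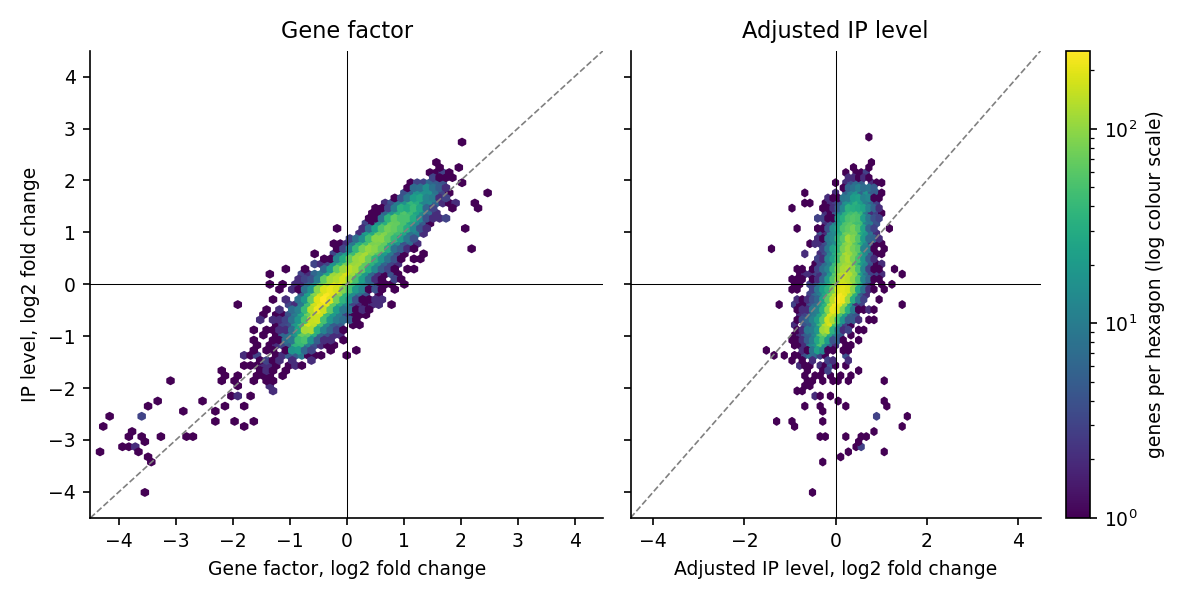
Log2 fold changes (nano-TiO2 over sham) of the IP level against those of the gene factor (left) and of the adjusted IP level (right) for 13806 genes, as genes per hexagon on a log colour scale; the dashed line marks equal changes. Points lie along the dashed line on the left (r = 0.933), and the adjusted changes on the right are narrower, with an SD across genes of 0.27 against 0.70 for the IP level.

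At the resolution of windows, 250317 windows with a mean of at least 10 normalized reads were tested, and 28052 passed in 3343 of 8877 genes (limma). Of these, 9718 rose and 18334 fell. Windows of called genes made up 94.1% of the called windows and 33.6% of all windows tested. The direction of the balance depended on scaling and on the level filter. Rises made up 34.6% of calls with the deposited scaling, 66.1% of 20784 after TMM and 77.1% of 11004 after quantile normalization. They made up 51.4% of 27133 among windows with a mean of at least 1 and 11% of 22337 among those with a mean of at least 50. Leaving out a library lowered the count to 12114 without sham replicate 1, 17866 without sham replicate 2, 13155 without nano-TiO2 replicate 1 and 13744 without nano-TiO2 replicate 3.

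In the adjusted values, 8 of 253327 windows passed, in 7 genes (limma; 24602 windows had an unadjusted p under 0.05). The count was 0 among windows with a mean of at least 50, and it was 2 without sham replicate 1, 30 without sham replicate 2, 2 without nano-TiO2 replicate 1 and 4 without nano-TiO2 replicate 3. Simulated 4-fold changes in single adjusted windows were recovered by this test in 19.7% of cases and 2-fold changes in 0%.

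A further test asked whether IP signal moved within genes, comparing each window's change with that of its gene. Of 249423 windows, 116 passed in 90 genes (limma diffSplice), 93 of them with relatively more signal in nano-TiO2, and the median absolute log2 difference was 1.36. By Simes' method, 67 of 7983 genes had such a window. None of the 116 lay in the 4 most abundant genes. On simulated reads this test called 83 windows, of which 21 were unchanged. The test takes the windows of a gene as independent. Windows start 25 nucleotides apart and fragments are 250 to 350 nucleotides long, so neighbouring windows may vary together. In each library 2801 to 2936 genes held exactly 1 read over all their windows, so reads there were not counted in several windows. The simulated windows were drawn independently, so the 21 do not measure false calls from neighbouring windows that vary together. The count was 10 among windows with a mean of at least 50 and 656 among windows with a mean of at least 1.

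The position of IP signal along genes was compared because m6A lies mostly near stop codons and in 3′ untranslated regions. The last 25% of each gene's windows held 24.2% ± 0.11 of reads in nano-TiO2 and 22.9% ± 1.0 in sham (SD, n = 3; exact two-sided permutation p = 0.1, adjusted p = 0.131). The first 25% held 23.6% ± 0.74 in nano-TiO2 and 22.3% ± 0.42 in sham (SD, n = 3; exact permutation p = 0.1). Which end of the window order is the 3′ end was not established, nor whether it is the same end in every gene. Mean coverage was raised near both ends. The comparison therefore cannot say whether signal near stop codons or in 3′ untranslated regions differed. As a mean over genes the difference in the last 25% was -0.361 percentage points (exact permutation p = 0.3), and outside the 4 most abundant genes it was 0.445 points against 1.27 over all genes. Without sham replicate 2 it was 0.713 points.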

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

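The tests of the gene factor, equal totals, the length trend and the 4 most abundant genes were chosen only after the data were seen. The count of genes called for IP level stayed within 1.5 times of 6676 under 20 alternatives (4666 to 9370), one of which is an identical table, but the genes differed: of the 6676, 3118 were called with the same sign with the length trend removed, 4595 after quantile normalization and 4611 with equal totals. The count was 2801 with the median of a gene's windows (26% rises), for which 8877 genes had a tested window. The adjusted level gave 0 genes except 2 with the median of windows, 5011 with array quality weights and 1878 without sham replicate 2; the range on leaving out a library was 0 to 1878. The gene factor gave 4979 genes, 8065 with weights, 1841 with the length trend removed and 0 to 4708 on leaving out a library. IP windows numbered 28052, 11004 after quantile normalization and 12114 to 21647 on leaving out a library. Adjusted windows numbered 8, 3 at a mean of at least 1, 0 at a mean of at least 50, 15 with weights and 2 to 30 on leaving out a library. Windows called within genes numbered 116, 58 with a pseudocount of 5, 656 at a mean of at least 1 and 10 at a mean of at least 50. The difference in the last 25% of windows was 1.27 points and -0.361 as a mean over genes. ENSMUSG00000069919 went from -1.44 to 0.23 after quantile normalization, which is not past the threshold. Fewer samples enter when a library is left out, and other filters test other numbers of windows; otherwise the cause was not tested.

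What same-numbered libraries share beyond the number is not stated, and a shared handling step is not ruled out. Their deviations correlated at -0.41, 0.28 and 0.12 for IP level and at 0.08, 0.05 and 0.11 for adjusted level. With the number as a replicate block, the counts were 6415 genes and 31744 windows for IP level, 0 genes and 125 windows for adjusted level, 1793 genes for the factor (1362 higher, 431 lower) and 106 windows within genes; an exact sign-flip test of the last 25% gave p = 0.25, the smallest 3 differences allow. The table named filtered gave the same values, being identical. A count test of the adjusted values without the factor as an offset, and every alternative for the gene lists, were not run.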

Other observations

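The counts of called genes and windows for IP and adjusted level, and those without a library, were planned; the tests of the factor, gene length, standard errors and thinning in this part were chosen only after the results were seen. In sham replicate 2 the 4 genes with the most reads all had high factors (1.95 to 2.42) and in nano-TiO2 replicate 2 all had low ones (0.253 to 0.393). In each of the 6 libraries they formed 2 pairs. In sham replicate 3 the factors were 0.803 and 0.783 for ENSMUSG00000069917 and ENSMUSG00000069919 and 1.29 and 1.30 for ENSMUSG00000073940 and ENSMUSG00000052305, and in sham replicate 1 they were 1.09 and 1.1 against 0.856 and 0.807. Dividing by the factor narrowed their joint share from 8.03% to 35.2% of reads to 17.6% to 23.8% of adjusted values over the 6 libraries. Their log2 factor changes were -1.22 to -1.18 and did not pass the threshold (adjusted p 0.068 to 0.095, limma).

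With 3 libraries against 3 there are 10 splits, so the share of splits with a result as large is never under 0.1. For IP level per gene the real split gave 6676 genes and the highest other split 0; it was the largest in 1 of 10. The counts were 4979 and 31 for the factor, 28052 and 43 for IP windows and 116 and 24 for windows within genes, each the largest in 1 of 10. For adjusted level the real split gave 0 genes as did the 10 splits, and 8 windows, reached or passed by 3 of 10 with 24 in the highest other. The correlation of IP and factor changes was 0.933 against 0.899 at most in another split, and the rank correlation with gene length 0.548 against 0.497.

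The first pattern is that 6676 genes differed in IP level and 0 in adjusted level. The errors of the adjusted values were not larger in absolute terms: the median standard error of an adjusted change was 0.91 times that of an IP change. The changes were smaller too, with a median absolute log2 change of 0.25 for adjusted level and 0.5 for IP level. Errors were thus larger relative to the changes, and lower power for adjusted level stays open. Whether IP differences follow a separate quantity behind the factor, such as the transcript level, stays open: the correlation of 0.933 across genes largely restates that adjusted changes are small, because the factor is the normalized over the adjusted value. A remaining difference in adjusted level may be masked by sham replicate 2, without which 1878 genes passed, while leaving out any other library gave 0. The source of the factor is not stated, and whether exposure or another difference between the pools set it was not tested.

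The second pattern is the rise of the IP fold change with gene length. Background reads spread evenly over genes in the nano-TiO2 libraries would raise long genes mainly where levels are low. From the 20% of genes with the lowest level to the 20% with the highest, the slopes per doubling of windows were 0.249, 0.306, 0.342, 0.333 and 0.289. A slope thus remained at the highest levels, where such background would add little. The slope of the lowest group may be understated by the log2(value + 1) scale, and slopes fell from the middle group upward. A contribution of background at lower levels therefore stays open. The rank correlation of factor change with length was 0.556, which would argue against the immunoprecipitation step alone if the factor came from other libraries, but its source is not stated and this stays open. RNA quality or library preparation shared by the libraries of a group could give the trend, and it cannot be told apart from exposure, since the slopes of the groups do not overlap (exact permutation p = 0.1) and no label gives a batch. A change of long and short transcripts with exposure stays open.

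The third pattern is that nano-TiO2 libraries held reads in more windows. Depth does not account for it: at equal depth the difference in windows with a read was 351735, against 309980 before thinning. Reads taken by the 4 most abundant genes may account for part of it at most, since at equal depth outside these genes the difference was 293688 and the groups still did not overlap. A broader set of transcripts in the exposed hearts and a difference in library preparation both stay open, and other differences between the pools were not tested.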
